A study of Sus scrofa with 9 samples.

How the data were processed

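The samples were cultures of IPEC-J2, an epithelial cell line from the jejunum of a newborn pig. Per the labels' protocols, confluent cells received medium alone or Salmonella Choleraesuis, a serovar adapted to swine, for 1 h at a multiplicity of infection given as 1:10. Extracellular bacteria were then removed and infected cultures stayed for 2 or 4 h in gentamicin at 50 µg/ml, an antibiotic that does not enter the cells. RNA was taken with a column kit and biotinylated cRNA was made from 5 µg of total RNA for an Affymetrix porcine array. The labels give 3 groups of 3 arrays: uninfected cells labelled 0 h, infected cells at 2 h and infected cells at 4 h. The design text says that the experiment was run in triplicate but not whether the 3 cultures came from separate days or passages, so p-values measure only the spread between these arrays, which may be technical. Uninfected cells at 2 h or 4 h and other serovars were not analysed here.

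The deposited values are log2 signals per probe set, normalised by the authors with RMA in R 2.7.0 per the submitters' processing notes. RMA subtracts background, brings the arrays to 1 distribution and summarises the probes of each probe set. A change shared by most transcripts is therefore removed, and changes of weak transcripts are compressed. The set of arrays that entered the normalisation together is not given in the sources used here. Array medians ran from 6.12 to 6.15, and no array held the values of another. Detection calls were not used here, so a low signal is not called absent, and for arrays their number limits the precision.

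Of 24123 probe sets, 124 controls were set aside and 23999 were tested. The platform annotation gave exactly 1 gene symbol to 10069 tested probe sets and several to 198. The remaining 13732 are unnamed here, and genes were named only from probe sets with 1 symbol. No symbol needed updating, and 9961 named probe sets matched the pig gene table of assembly Sscrofa11.1, used for names and gene spans and not for positions. This gave 6765 genes, 2261 of them with more than 1 probe set. Each gene was represented by its probe set with the highest mean over the 9 arrays.

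Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with the 9 arrays in 3 groups, no covariate and a shared spread. P-values were adjusted over the 23999 probe sets by the Benjamini-Hochberg method within each comparison. A probe set was called where its adjusted p was below 0.05. The 3 comparisons were 2 h against uninfected, 4 h against uninfected, and 4 h against 2 h. A limma F test over the 3 groups was adjusted in the same way. Values are given as mean ± SD over n = 3 arrays, and log2 changes with the standard error (SE) of the fit. All tests were two-sided.

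Before the data were examined, 22 gene lists were fixed. They cover cytokines and chemokines, NF-kappaB feedback and targets, immediate early genes and AP-1, EGF receptor ligands with prostaglandin and wound repair genes, the interferon response, antigen processing, pattern recognition, antimicrobial and mucosal defence, apoptosis, tight and adherens junctions, sterol synthesis, endoplasmic reticulum stress, heat shock, oxidative stress, glycolysis and hypoxia, the cell cycle, enterocyte differentiation, autophagy and lysosome, cytosolic ribosomal proteins, and markers of leukocytes and of fibroblasts and endothelium. The result of 1 further list is not reported here. Lists were tested with limma's camera on 1 probe set per gene at a preset correlation of 0.01, with adjustment over the 22 lists. Camera with an estimated correlation and limma's fry were alternatives. The rule for naming genes was fixed at the same time. It took the 10 largest called rises and falls at each time without overlap between the arrays compared, or 5 for 4 h against 2 h. It also took the 4 members with the smallest p in each called list and in 5 lists of prior interest, 1 member of every other list, and CXCL8, TNF, IL6, CCL20 and NFKBIA. A gene named outside this rule is said to be so. CCL20 has no named probe set here.

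The 2 h and 4 h changes share the uninfected arrays. Their correlation was therefore set beside 100 simulations of unchanged groups against the same controls. The ratio of 3' to 5' probe sets of the actin, GAPDH and EF1A controls was compared by an exact permutation test, whose smallest p with 3 against 3 arrays is 0.1. Alternatives set before the data were examined were the replicate number as a block, eBayes with trend and robust options, filters on dim probe sets, further scaling, a fit to only the 6 arrays compared, array weights, a minimum log2 change of 1, other probe sets of a gene, other list tests, and leaving out each array.

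The fit was tested on simulated data with the means and spreads of the real 23999 probe sets, 200 of them changed at 2 h, in 20 runs. It recovered 81.0% of changes of 0.5, 99.9% of changes of 1 and 100% of changes of 2 on the log2 scale, and 5.91% of calls were false. With no change simulated, a comparison had 0.167 calls on average. The simulated noise was independent between probe sets, so deviations that many probe sets of a real array share are absent. These rates may therefore not hold for the real arrays. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.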

Results

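Transcript levels were measured on 9 arrays, 3 of uninfected IPEC-J2 cells, 3 of cells at 2 h and 3 of cells at 4 h after a 1 h exposure to Salmonella Choleraesuis. The question was how the transcriptome of this porcine intestinal epithelial line responds to the bacterium. The uninfected arrays carry the label 0 h, so infection, time and handling change together in each comparison with them.

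At 2 h, infected cells held higher levels of transcripts for inflammatory mediators. IL1A, the cytokine interleukin 1 alpha, rose from a log2 signal of 7.27 ± 0.22 to 10.40 ± 0.24 (SD, n = 3 each), which is 8.75-fold. CXCL2, a chemokine for neutrophils, rose 8.16-fold, from 8.86 ± 0.37 to 11.89 ± 0.10. CXCL8, which encodes interleukin 8, the protein that the study measured in the medium by ELISA, rose 4.21-fold, from 9.81 ± 0.18 to 11.88 ± 0.18. The limma adjusted p was 1.14e-06 for IL1A, 4.59e-06 for CXCL2 and 7.85e-06 for CXCL8.

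Other large rises at 2 h were of IRF1, NFKBIA, SNAI1, LIF, EDN1, ITGA2 and MANBAL. IRF1, an interferon regulatory factor, rose by 2.22 ± 0.15 on the log2 scale (SE), and NFKBIA, the inhibitor that retains NF-kappaB in the cytoplasm, by 1.88 ± 0.10. SNAI1, a repressor of epithelial genes, rose by 1.55 ± 0.12, and the cytokine LIF by 0.97 ± 0.13. EDN1, the precursor of endothelin, had a log2 change of 1.41 ± 0.29, and the collagen receptor subunit ITGA2 of 1.41 ± 0.24. The call of EDN1 was lost, with an adjusted p of up to 0.158, without any single array other than uninfected replicate 3. Another probe set of ITGA2 had 0.37 (adjusted p = 0.204), and the call of ITGA2 was lost, with an adjusted p of up to 0.1003, without uninfected replicate 1 or 2 or any single 2 h array. MANBAL completed the 10 largest rises of named genes with 1.20 ± 0.11. The falls were smaller. The 10 largest, of FUBP3, DARS, VCPIP1, KIAA0232, ACVR2A, ZCCHC9, TMEM263, TSC22D3, FAM118B and BROX, lay between -0.54 and -0.36, and DARS is the aspartyl-tRNA synthetase. Other probe sets of ACVR2A, ZCCHC9 and TSC22D3 had -0.02, -0.05 and -0.03 at 2 h, with adjusted p of 0.956, 0.872 and 0.904. The falls of these genes and of DARS did not pass on the mean of their probe sets, with adjusted p from 0.0652 to 0.0977. Apart from DARS and ZCCHC9, each of the 10 falls lost its call in 6 to 9 of the 9 fits without 1 array, in every case without 2 h replicate 1, 2 h replicate 2 and 4 h replicate 3, with highest adjusted p between 0.107 and 0.146.

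Of 26 measured cytokine and chemokine genes, 6 rose at 2 h, none fell and 20 did not pass the test, and 7 rose when adjusted over the list alone. Besides IL1A, CXCL2, CXCL8 and LIF these were IL6, with a log2 change of 0.69 ± 0.12, and TNF, with 0.56 ± 0.09. The list was called higher (camera adjusted p = 2.97e-05), with an adjusted p = 0.547 with an estimated correlation. Its median log2 change was only 0.08 against a mean of 0.46, so a few large rises carried much of the shift. In the NF-kappaB list, 3 of 13 genes rose, namely IRF1, NFKBIA and the adhesion molecule ICAM1 (0.75 ± 0.11), and 6 rose adjusted over the list alone. Its camera adjusted p was 9.70e-05, and the adjusted p was 0.234 with an estimated correlation. The median log2 change of this list was 0.07 and its mean 0.44. Of 28 immediate early genes, 2 rose, ZFP36, whose product destabilises cytokine mRNAs, by 0.77 ± 0.10, and BTG2 by 0.84 ± 0.18, and 3 rose adjusted over the list alone. The call of BTG2 was lost, with an adjusted p of up to 0.141, without any single array other than 2 h replicate 1. The immediate early list had a camera adjusted p of 0.000661 and an adjusted p of 0.811 with an estimated correlation. Other splits of the same 6 arrays called up to 6 lists, against 3 here.

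The remaining 19 lists were not called at 2 h, with camera adjusted p from 0.841 to 0.917. No gene of the interferon list passed the main test among 26 measured. IRF7 had 0.39 ± 0.10 (adjusted p = 0.0815), with an adjusted p of 0.0349 on the mean of its 2 probe sets. It also passed with the replicate number as a block. Of 14 junction genes 1 rose, JUP, which encodes plakoglobin, by 0.74 ± 0.12. The call of JUP was lost, with an adjusted p of up to 0.0851, without uninfected replicate 1 or 2 or any single 2 h array. Of 22 apoptosis genes 1 rose, the survival factor BCL2L1, by 0.51 ± 0.10. Its other probe set had 0.36 (adjusted p = 0.123), and its call was lost, with an adjusted p of up to 0.122, without uninfected replicate 1 or 2, any single 2 h array or 4 h replicate 3. None of the 25 antimicrobial, 58 ribosomal protein, 21 leukocyte or 23 fibroblast and endothelial genes passed, and neither did any gene of the other 11 lists on its probe set with the highest mean. PDIA3, of the antigen processing list, had -0.26 (adjusted p = 0.0640) on that probe set and -0.66 (adjusted p = 0.00451) on another, and the mean of its probe sets passed, as did that of ATP6V1A, of the autophagy list. Adjusted over the list alone, 1 gene rose in each of the apoptosis, junction, sterol, heat shock, glycolysis and fibroblast lists, and 1 fell in each of the antigen processing, cell cycle and autophagy lists. Median, mean and test differed in sign for the interferon, antimicrobial, apoptosis, heat shock and oxidative stress lists.

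Over all probe sets, 330 of 23999 were called at 2 h, 231 higher and 99 lower, and 23 rises and 1 fall reached 2-fold. These held 102 named genes that rose and 15 that fell. The largest rise, of 5.06 ± 0.18 on the log2 scale, belonged to a probe set that is unnamed here. The count was 116, 114 and 201 without uninfected replicate 1, 2 and 3, 138, 81 and 76 without 2 h replicate 1, 2 and 3, and 158 without 4 h replicate 3. Of the genes called at 2 h, the 28 that the naming rule picked for this comparison were followed without single arrays. Of these 12 were called whichever array was left out, including CXCL2, CXCL8, DARS, IL1A, IRF1, LIF, MANBAL, NFKBIA, SNAI1, ZCCHC9 and ZFP36, and the other 16 lost the call without at least 1 array, with their highest adjusted p between 0.0502 and 0.158. Among these were IL6 (up to 0.0961) without uninfected replicate 2 or 3 or 2 h replicate 2 or 3, and TNF (up to 0.0685) without uninfected replicate 1 or 2 h replicate 2. Uninfected replicate 3 also had the lowest hybridisation controls, at 8.73.

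**Figure D1:**
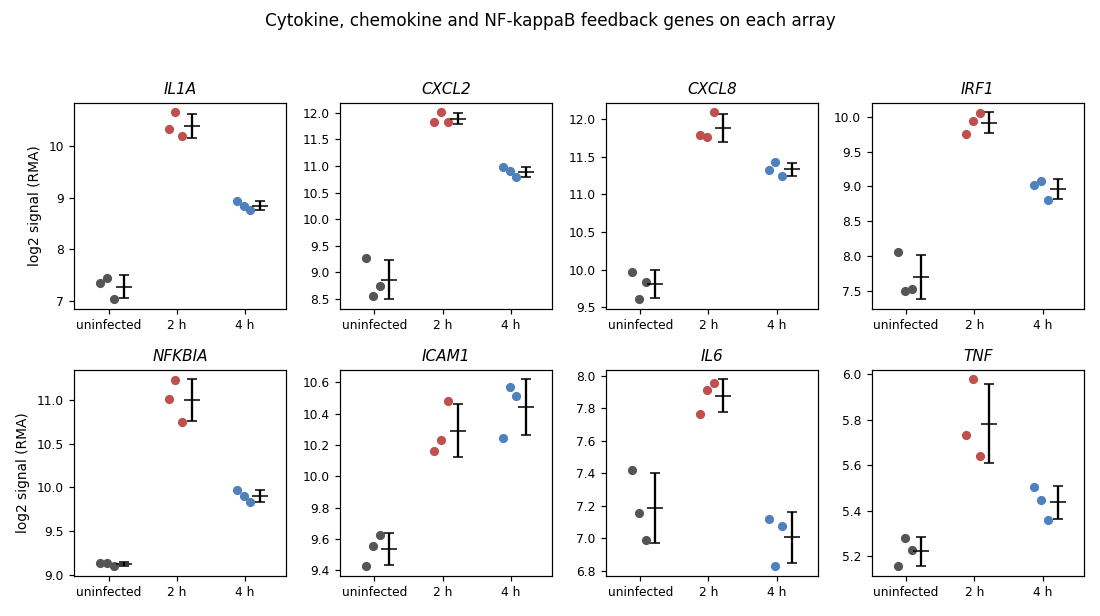
Log2 signal of 8 genes on each of the 9 arrays, by group (points), with the mean and SD of the 3 arrays (black bar). IL1A, CXCL2, CXCL8, IRF1 and NFKBIA were highest at 2 h and remained above uninfected cells at 4 h, while IL6 averaged 7.19 in uninfected cells and 7.88 at 2 h and had a change of -0.18 from uninfected cells at 4 h.

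At 4 h, CXCL2, IL1A and CXCL8 were still above uninfected cells, and 10 of 28 immediate early genes lay below them. CXCL2 rose by 2.03 ± 0.15 on the log2 scale, IL1A by 1.57 ± 0.13, CXCL8 by 1.53 ± 0.11 and IRF1 by 1.27 ± 0.15 (SE, 3 arrays per group). DUSP6, the phosphatase that limits ERK signalling and a target of it, fell by 1.42 ± 0.10, from 11.21 ± 0.12 to 9.79 ± 0.19 (SD). FOS, a subunit of the AP-1 transcription factor, fell by 1.10 ± 0.24, and HBEGF, a ligand of the EGF receptor, by 0.77 ± 0.15.

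The other genes among the 10 largest rises were ITGA2 (1.57 ± 0.24, and 0.50 on another probe set), CHI3L1, a secreted chitinase-like protein (1.54 ± 0.28), MANBAL (1.22 ± 0.11), the RNA helicases DHX9 (1.06 ± 0.12) and DDX46 (1.00 ± 0.17), and the cyclophilin PPIG (0.97 ± 0.16). A second probe set of DDX46 had a log2 change of -0.17 with an adjusted p of 0.380, and that of PPIG had 0.18 with 0.400. The other large falls were of FUBP3 (-0.99 ± 0.10), ANKRD44 (-0.93 ± 0.10), MLLT3 (-0.82 ± 0.10), HES1 (-0.80 ± 0.16), THNSL1 (-0.80 ± 0.21), DDIT3, the stress factor CHOP (-0.79 ± 0.15), and GADD45A, which is induced by growth arrest and DNA damage (-0.77 ± 0.13). The fall of MLLT3 rests on 1 of its 2 probe sets, since the other had an adjusted p of 0.998, and a second probe set of DUSP6 had -0.58 with an adjusted p of 0.211.

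Of 28 immediate early genes, 10 fell at 4 h, none rose and 18 did not pass, and 15 fell and 1 rose adjusted over the list alone. Besides DUSP6, FOS, GADD45A and HES1, the list held KLF10 at -0.75 ± 0.08 and IER2 at -0.53 ± 0.09. The median of the list was -0.30, with a camera adjusted p of 1.97e-07 and an adjusted p of 0.367 with an estimated correlation. In the NF-kappaB list 6 of 13 genes rose, over all probe sets and adjusted over the list alone. ICAM1 rose by 0.91 ± 0.11, NFKBIA by 0.78 ± 0.10 and TNIP1, a partner of the A20 deubiquitinase, by 0.44 ± 0.07. Its camera adjusted p was 0.00131, and the adjusted p was 0.367 with an estimated correlation. Other splits of the same 6 arrays called up to 6 lists, against 2 here.

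The cytokine list was not called at 4 h (camera adjusted p = 0.410). In it 3 of 26 genes rose, CXCL2, IL1A and CXCL8, while IL6 had -0.18 ± 0.12 and TNF 0.22 ± 0.09, with adjusted p of 0.389 and 0.181. In the interferon list 2 of 26 genes rose, the receptor subunit IFNAR2 (0.82 ± 0.21) and IRF7 (0.49 ± 0.10), and SAMHD1 fell (-0.27 ± 0.07). All 3 calls were lost without some arrays, that of IRF7 (up to 0.0669) without uninfected replicate 1 or 4 h replicate 2 or 3, that of IFNAR2 (up to 0.134) without any single array other than 2 h replicate 1 or 3, and that of SAMHD1 (up to 0.1205) without any single array other than 2 h replicate 1. JUP was the only 1 of 14 junction genes to pass, with 0.68 ± 0.12, and CDH1 and CLDN4 each had 0.14 with adjusted p of 0.255 and 0.353. Of 25 oxidative stress genes 2 rose, with the glutathione peroxidase GPX1 at 0.69 ± 0.08, and of 22 heat shock genes 2 rose, with the regulator HSF1 at 0.33 ± 0.06. DDIT3 was the only 1 of 19 endoplasmic reticulum stress genes to pass.

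The other lists moved in few members. In the EGF receptor ligand and wound repair list 1 of 20 genes rose and 2 fell. Of 22 pattern recognition genes 2 rose, among them TOLLIP (0.34), and MAP3K7 fell (-0.25). Of 22 apoptosis genes 1 rose and 2 fell, with DFFA at -0.31, and at -0.05 and -0.28 on its other probe sets, with adjusted p of 0.694 and 0.0552. Of 28 autophagy and lysosome genes 1 rose and 2 fell, with ATP6V1A at -0.31. In the antigen processing list PDIA3 fell (-0.24, and -0.64 on another probe set with an adjusted p of 0.00290), in the cell cycle list CDKN1B fell (-0.36, with 0.16 on another probe set that did not pass), in the sterol list SCAP rose (0.31), in the glycolysis list SLC2A3 rose (0.50) and in the fibroblast and endothelial list THY1 rose (0.46). Without 1 array, CDKN1B, MAP3K7 and PDIA3 each lost the call in 7 of 9 fits and THY1 in 5, with adjusted p up to 0.126. SCAP and ATP6V1A lost it in 4, and SLC2A3 and DFFA in 3. No antimicrobial, enterocyte, ribosomal protein or leukocyte gene passed. Adjusted over the list alone, 3 antigen processing genes rose and 1 fell, 2 genes rose and 2 fell in each of the EGF receptor ligand and apoptosis lists, and no cell cycle gene passed, while the counts of the other lists named here did not differ. The 20 lists not called had camera adjusted p from 0.410 to 0.904, and median and test differed in sign for the interferon and autophagy lists.

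At 4 h, 1774 probe sets were called, 780 higher and 994 lower, a balance that turned to 944 higher and 869 lower with each array centred on its median and to 614 higher and 582 lower without uninfected replicate 3. Of the 1774, 21 rises and 9 falls reached 2-fold. They held 289 named genes that rose and 239 that fell, and 37.1% of the probe sets that fell had a name, against 42.0% of all tested. The median gene span was 13.6 kb for named genes that rose and 44.4 kb for those that fell, and removing a trend with span on each array, chosen after the data were seen, changed the number of rises from 387 to 258 and of falls from 294 to 291 in a fit to the 6694 genes with a span. The count was 631 without uninfected replicate 1, 727 without 4 h replicate 2 and 596 without 4 h replicate 3, and 1196 without uninfected replicate 3, whose hybridisation controls were the lowest. Of the 40 called genes that the naming rule picked for this comparison, 16 lost the call without at least 1 array, with their highest adjusted p between 0.0523 and 0.140. Among these were FOS (up to 0.0927) without uninfected replicate 1 or 2 or any single 4 h array, HES1 (0.0630) without uninfected replicate 1, CHI3L1 (up to 0.0523) without uninfected replicate 1 or 4 h replicate 3, and DDIT3 (up to 0.0593) without uninfected replicate 1 or 4 h replicate 2 or 3. THNSL1 lost its call in 6 of the 9 fits without 1 array, with an adjusted p of up to 0.140.

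**Figure D2:**
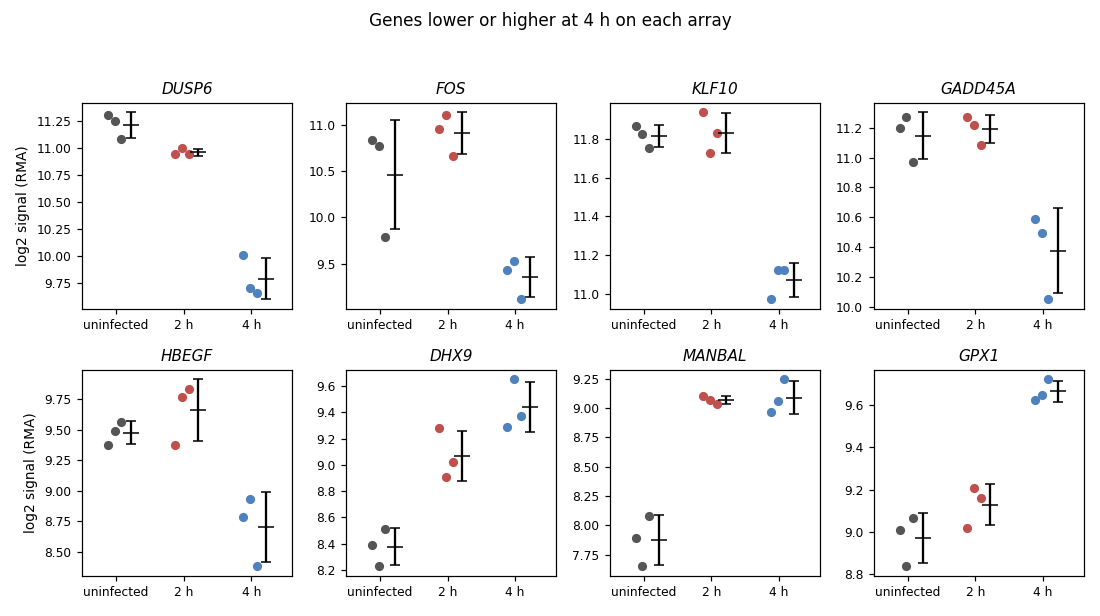
Log2 signal of 8 genes on each of the 9 arrays, by group (points), with the mean and SD of the 3 arrays (black bar). DUSP6 averaged 11.21 in uninfected cells, 10.96 at 2 h and 9.79 at 4 h, and GPX1 averaged 8.97, 9.13 and 9.66.

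Between 2 h and 4 h of infection, 4 of 26 cytokine genes and 11 of 28 immediate early genes fell. IL1A fell by 1.55 ± 0.13 on the log2 scale, FOS by 1.55 ± 0.24, SNAI1 by 1.35 ± 0.12, DUSP6 by 1.17 ± 0.10 and ID1, an inhibitor of differentiation factors, by 1.13 ± 0.15 (SE, 3 arrays per group). NFKBIA fell by 1.10 ± 0.10 and IL6 by 0.87 ± 0.12, with adjusted p of 0.00152 and 0.00994. The change of CXCL8 did not pass the test (-0.54 ± 0.11, adjusted p = 0.0704), and neither did that of TNF (-0.35 ± 0.09, adjusted p = 0.155). The named genes that rose were SGK1, a kinase that regulates ion transport (0.68 ± 0.11), GPX1 (0.54 ± 0.08), VCPIP1 (0.48 ± 0.09) and ZNF7 (0.44 ± 0.08), and each of these 4 calls was lost without at least 1 array.

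Of the 28 immediate early genes, 11 were lower at 4 h than at 2 h and none higher, and 21 were lower adjusted over the list alone. The median change of the list was -0.57, with a camera adjusted p of 2.51e-25 and an adjusted p of 0.0477 with an estimated correlation. Of the 26 cytokine genes 4 fell, CXCL2, IL1A, IL6 and LIF, and 9 fell adjusted over the list alone. The cytokine list had a camera adjusted p of 0.000224 and an adjusted p of 0.543 with an estimated correlation. In the NF-kappaB list 2 genes fell, NFKBIA and IRF1, and its median was 0.07 while its mean was -0.10 (camera adjusted p = 0.712). HBEGF, DDIT3 and GPX1 were the only genes of the other lists to pass, and the 20 lists not called had camera adjusted p from 0.134 to 0.903. Adjusted over the list alone, 3 oxidative stress genes rose, 2 NF-kappaB genes fell, 1 gene rose and 2 fell in the apoptosis list, 1 rose and 1 fell in the EGF receptor ligand list, and 1 fell in each of the endoplasmic reticulum stress and cell cycle lists. Median, mean and test differed in sign for the NF-kappaB, EGF receptor ligand, interferon, apoptosis, sterol, enterocyte, autophagy, ribosomal protein and fibroblast lists. Other splits of the same 6 arrays called up to 6 lists, against 2 here.

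In all, 127 probe sets differed between 4 h and 2 h, 11 higher and 116 lower at 4 h, and 23 of the falls reached 2-fold. The count was 60, 46 and 61 without 2 h replicate 1, 2 and 3, and 54, 73 and 37 without 4 h replicate 1, 2 and 3. The number of rises, 11 over all arrays, was 0, 1 and 5 without 2 h replicate 1, 2 and 3, 3, 3 and 0 without 4 h replicate 1, 2 and 3, and 6 without uninfected replicate 2. Of the 11 called genes that the naming rule picked for this comparison, DUSP6, IL1A, NFKBIA and SNAI1 were called whichever array was left out. The others reached an adjusted p between 0.0536 and 0.207, among them IL6 (0.0536) without 2 h replicate 2, ID1 (up to 0.0664) without 2 h replicate 2 or 4 h replicate 3, and FOS (up to 0.112) and GPX1 (up to 0.0962) without any single 2 h or 4 h array. SGK1 (up to 0.127) lost its call without any single 2 h array or 4 h replicate 2 or 3, VCPIP1 (up to 0.181) without uninfected replicate 2 or 3, any single 2 h array or 4 h replicate 1 or 3, and ZNF7 (up to 0.207) without any single array.

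**Figure D3:**
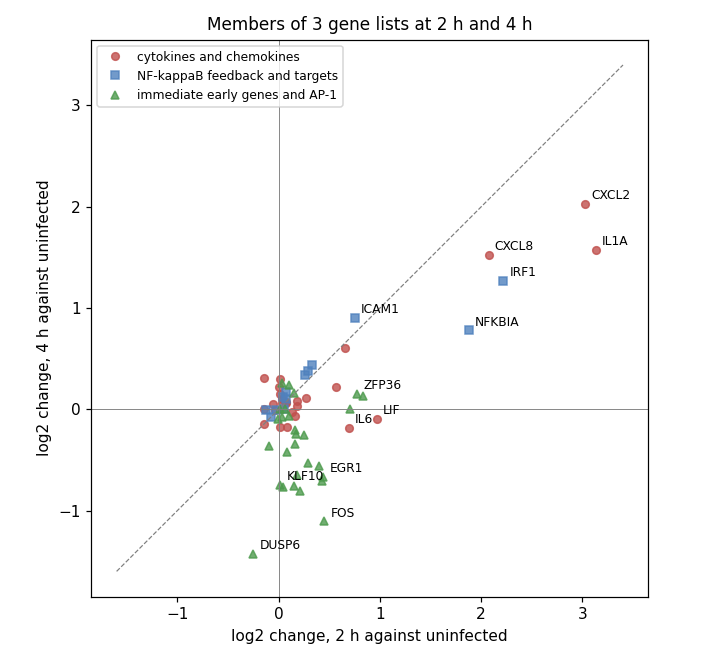
Log2 change at 4 h against log2 change at 2 h, each relative to uninfected cells, for the measured members of 3 gene lists, with the line of equal change (dashed). IL1A lies at 3.13 and 1.57, CXCL2 at 3.03 and 2.03, and DUSP6 at -0.25 and -1.42.

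Genes that moved at 2 h mostly moved the same way at 4 h. Of the 231 probe sets higher at 2 h, 189 were also higher at 4 h, where independent lists would share 7.51, and 1 was lower. Of the 99 lower at 2 h, 65 were also lower at 4 h, where 4.10 would be shared by independent lists. These expectations leave out that both comparisons use the same uninfected arrays. The share of all probe sets with the same sign at both times was 74.0%, against 66.6% in a simulation with shared simulated controls and no change. MANBAL was an example of a rise of like size, with 1.20 and 1.22. The changes over all 23999 probe sets, which are not independent replicates, had a Pearson r of 0.686, where simulated unchanged groups with shared simulated controls gave 0.50. The covariance of the 2 h and 4 h changes was 0.0231, against 0.00485 in simulation. Deviations that many probe sets of a real array share are absent from the simulation, so it cannot give the size of the excess over these controls. With 3 uninfected arrays the controls could not be split into parts of 2 arrays, so part of the excess may come from the shared controls.

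The F test over the 3 groups called 1165 probe sets. That count was 374, 642 and 704 without uninfected replicate 1, 2 and 3, 713 and 671 without 2 h replicate 2 and 3, and 666, 501 and 360 without 4 h replicate 1, 2 and 3. Arrays of 1 group correlated at 0.9965 to 0.9980, and arrays of uninfected and 4 h cells at 0.9945 to 0.9962. The first principal component held 32.0% of the variance and ran from uninfected arrays (-19.1 to -13.3) over 2 h arrays (-2.80 to 7.13) to 4 h arrays (11.3 to 15.2).

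The 3' to 5' difference of the actin, GAPDH and EF1A controls, a sign of RNA integrity, averaged 0.30 ± 0.06 in uninfected cells, 0.25 ± 0.02 at 2 h and 0.21 ± 0.02 at 4 h (log2, SD, n = 3). Exact permutation tests gave p = 0.3 at 2 h and p = 0.2 at 4 h, where 0.1 is the smallest possible. At 4 h the difference was lower on every infected than on every uninfected array for actin (by -0.16 on average) and for GAPDH (-0.088), each with an exact permutation p of 0.1, and EF1A had -0.026 with an exact p of 0.5. The bacterial hybridisation controls added to each array averaged 9.50 ± 0.67 on uninfected, 10.09 ± 0.06 on 2 h and 10.13 ± 0.08 on 4 h arrays. On uninfected replicate 3 they stood at 8.73.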

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

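The tests of ribosomal protein genes, of time-matched uninfected arrays, of the array correlation and of the span trend as the whole cause of the calls were chosen after the results were seen. The span trend was looked for after the names of called genes had been read, and the test of the 4 control transcripts replaced an earlier one whose values had been seen and was computed again, under the same limit, after an error in assigning probe sets to transcripts was corrected.

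Changes from uninfected cells differed between 2 h and 4 h, by the limma test of 4 h against 2 h, for 22 of the genes that the naming rule picked. Cytokine genes came down from their 2 h level, with a difference of -1.55 for IL1A, -1.06 for LIF, -0.998 for CXCL2 and -0.87 for IL6. The same held for SNAI1 (-1.35), NFKBIA (-1.10), IRF1 (-0.95) and ZFP36 (-0.62). Genes that were not called at 2 h and had fallen at 4 h included FOS (-1.55), ID1 (-1.13), HES1 (-1.01), HBEGF (-0.96), IER2 (-0.83), DDIT3 (-0.82), GADD45A (-0.82), KLF10 (-0.76), DUSP6 (-1.17) and MLLT3 (-0.70, with 0.01 on its other probe set). Higher at 4 h than at 2 h were SGK1 (0.68), GPX1 (0.54), ZNF7 (0.44) and VCPIP1 (0.48), the last of which had fallen at 2 h and stood at -0.02 from uninfected cells at 4 h. The immediate early list and the cytokine list also differed between the times, with medians of -0.57 and -0.078, and the cytokine call was lost with an estimated correlation (adjusted p = 0.543) and with fry (adjusted p = 0.0827).

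Of 28 immediate early genes, 10 were called below the uninfected level at 4 h, among them DUSP6, FOS, KLF10 and GADD45A. The call of FOS was lost without some single arrays, and that of the list with an estimated correlation (camera adjusted p = 0.367). Scaling of the 4 h arrays was examined with the cytosolic ribosomal protein genes, whose median was -0.013 while that of the immediate early genes was -0.30. RMA brings the arrays to 1 distribution, and ribosomal protein genes such as RPS9 lie near its top. Their median therefore cannot exclude scaling at other signal levels. When a trend with gene span was removed from each array, all 11 immediate early genes that fell among the 6694 genes with a span stayed called. Removal made most of these falls larger, as for DUSP6 (-1.42 to -1.48), and that of ATF3 slightly smaller (-0.43 to -0.42). The trend raised short genes and so could hardly have ended these calls, and their staying is not counted as support. It also stays open that the uninfected cells were handled for another time than the infected cells. With 0 uninfected arrays at 2 h or 4 h, infection and time in culture cannot be told apart for the immediate early genes. The lower 3' to 5' difference of the actin and GAPDH controls on the 4 h arrays runs with the group too, and was not tested as a cause.

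Many genes changed by small amounts, and over 6694 named genes with a span (98.95% of all named) short genes tended to rise. The median span was 13.6 kb for genes that rose at 4 h and 44.4 kb for those that fell, and the Spearman rho between span and log2 change across genes, which are not independent replicates, was -0.18 at 4 h and -0.14 at 2 h, while another split of the 6 arrays at 4 h reached 0.214 in size. In a fit to these genes, removing the trend on each array kept 517 of 681 calls at 4 h (75.9%), changing 387 rises to 258 and 294 falls to 291. The median absolute log2 change of the called genes was 0.348 before and 0.340 after removal. A trend this small accounts for little of their size. It could hardly have ended most calls, so the number kept does not decide whether the trend was their whole cause. Without uninfected replicate 3, 1196 probe sets were called, narrowly above the limit set beforehand for the count. Only 1045 of them were among the 1774 called with all arrays, so the count does not exclude that array as a source of part of the calls. Part of the small rises at 4 h may still follow a span trend that varies between arrays, because the difference between short and long genes was higher on each infected array than on each uninfected one but by only 0.057 on average at 4 h, with a range of 0.037 within the uninfected arrays. Infection stays an untested biological explanation of that trend.

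The hybridisation controls, which the comparisons do not use, were higher on every infected array than on every uninfected array, by at least 0.10 on the log2 scale. The gap was widest on uninfected replicate 3, where all 27 control probe sets were at their lowest and their mean lay 1.33 below the median array (-1.33). Whether this is a poor array stays open, since correlations of whole arrays were too close to 1 to decide: its lowest within its group was 0.00073 below the lowest of the other pairs within a group, and its fitted array weight, 0.624, was the lowest of the 9. Less control mix relative to sample RNA is a candidate explanation, because bioB, bioC, bioD and cre shifted by amounts that differed by 0.61, only narrowly under the limit set beforehand, and the poly-A controls moved by 0.009. No biological explanation was tested for these controls.

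Other splits of the same 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. At 2 h the real split called 119 probe sets and the highest other 0, at 4 h 1185 and 0, and for 4 h against 2 h 83 and 0, so 1 of 10 splits reached the real count each time. For gene lists, 5 of 10 splits at 2 h called as many lists as the real 3, 6 of 10 at 4 h as many as the real 2, and 7 of 10 as many as the real 2 for 4 h against 2 h, and the highest other split called 6 lists in each comparison. The number of lists called was thus not larger than in splits that do not follow the groups. For the F test, 1 of 100 splits of the 9 arrays, the real one, reached 1165 calls and the highest other had 173. That argues against a random assignment of arrays to groups as the source of this count. Splits that mix the groups have a wider spread within them, which lowers their calls. Time, handling or another difference that runs with the groups is not tested in this way.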

How the results depend on the processing

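The removal of the gene span trend was added after the data were seen. The number of arrays limits what can be called, and signals near background are compressed. At 2 h the count of 330 was 525 with trend and robust options, 659 without the dimmest 50% of probe sets, 119 with only the 6 arrays compared and 24 with a log2 change of at least 1. At 4 h the count of 1774 was 30 with a log2 change of at least 1. For 4 h against 2 h the count of 127 was 221 with trend and robust options, 218 without the dimmest 50%, 83 with only the 6 arrays, 225 with array weights and 23 with a log2 change of at least 1. The F test called 1883 without the dimmest 50%. The added threshold accounts for the fold limit by construction. The filters and the 6-array fits change the number of tests or arrays and also the estimated spread, and which of these moved the counts was not tested. For the other settings the cause was not tested either. Leaving out single arrays gave 76 to 241 calls at 2 h, 596 to 1741 at 4 h, 37 to 121 for 4 h against 2 h and 360 to 944 in the F test.

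With an estimated correlation 0 lists were called at 2 h, 0 at 4 h and 1 for 4 h against 2 h, where fry also called 1. Leaving out single arrays called 3 to 3 lists at 2 h, 2 to 2 at 4 h and 2 to 3 between the times. The correlation of 0.686 between the 2 h and 4 h changes was 0.711 in the brighter 50%, 0.671 as Spearman's rho and 0.618 to 0.729 without single arrays. The 3' to 5' difference at 4 h of -0.09 was -0.16 for actin alone and -0.026 for EF1A alone. After removal of the span trend the number of genes called went from 181 to 168 at 2 h, from 681 to 549 at 4 h and from 56 to 63 between the times.

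Of 9 same-number pairs of arrays, 7 correlated above 0.1 in their deviations from the group means, the lowest at -0.20. In addition, 8 of 9 arrays correlated best with an array of their own number. The data thus hint at pairing by replicate number, which the main fit left out. With the replicate block the counts were 328 at 2 h, 2226 at 4 h and 233 for 4 h against 2 h, and the same numbers of lists were called. With it 242 of the 330 calls at 2 h, 1671 of 1774 at 4 h and 123 of 127 between the times were shared, and rises between the times went from 11 to 53. The block moved FAM118B and TSC22D3 at 2 h, CDKN1B at 4 h and VCPIP1 between the times out of the calls, and IRF7 (adjusted p = 0.0359) and THY1 at 2 h and CSF2 and ITGAM at 4 h into them. Named genes reversed only on another probe set, CDKN1B to 0.16 and DDX46 to -0.17 at 4 h. Without single arrays 839 named results stayed on their side of the threshold, 210 lost the call and 4 gained it, and none reversed. The 839 include results that were not called with all arrays. Among called genes, 16 of 28 at 2 h, 16 of 40 at 4 h and 7 of 11 between the times lost the call without at least 1 array.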

Other observations

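Genes outside the naming rule, chosen after their values were seen, showed 2 time courses. Each value is of the gene's probe set with the highest mean, and other probe sets and fits without 1 array are not given for these genes. CAPZB and CEBPD have 3 probe sets each and ELF3 has 2. STARD10, a lipid transfer protein, rose 1.89-fold at 2 h and 1.83-fold at 4 h. SPINT1, an inhibitor of serine proteases at the epithelial surface, rose 1.57-fold and 1.52-fold, and BSG, which encodes basigin, 1.52-fold and 1.47-fold. The actin capping subunit CAPZB rose by 0.80 and 0.79 on the log2 scale, the myosin MYO1C by 0.71 and 0.79, and the transcription factor CEBPD by 0.75 and 0.72. ELF3, an epithelial ETS factor, rose by 0.90 at 2 h and stood at -0.01 at 4 h, a decline of -0.91 between the times (adjusted p = 0.00414). SOCS3, which dampens cytokine receptor signalling, rose by 0.57 at 2 h and stood at -0.02 at 4 h, a decline of -0.60 (adjusted p = 0.0365).

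Falls at 4 h included the O-GlcNAc transferase OGT (-0.71), the membrane to actin linker RDX (-0.76), the nuclear export receptor XPO1 (-0.57), the TRAF binding protein TANK (-0.64) and PMAIP1, which encodes the death promoting protein NOXA (-0.73). Their adjusted p lay between 0.00543 and 0.0244. At 2 h none of these 5 passed the test. OGT has 4 probe sets and RDX, XPO1 and TANK have 2 each, of which only the one with the highest mean is given.

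DHX9, DDX46 and PPIG, linked to RNA processing, were among the 10 largest rises at 4 h. From these the hypothesis was drawn that RNA helicase and splicing factor genes rise together, and it was tested with camera on 74 other genes whose symbols begin with DDX, DHX, SRSF, HNRNP, SF3, PRPF or SNRP. HNRNPU, SF3A1 and SF3B4, already seen among the calls, were left out too, so the test covers 74 of the 79 measured genes with such symbols. The limma camera test at 4 h gave an adjusted p = 0.711 over the 3 comparisons. The median log2 change was 0.04, with 1 rise and 1 fall called, so the hypothesis was not borne out in these 74 genes. For 4 h against 2 h the camera direction was up, with an adjusted p of 0.110. Genes left out because they had been called could have carried a shift, so the test does not cover the families with them.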
